A study of Arabidopsis thaliana with 2 samples.

How the data were processed

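Single-cell RNA libraries were made from protoplasts, which are plant cells freed of their walls by enzymes, taken from the root tips of Arabidopsis thaliana (Col-0 ecotype) at 6 days of age. Per the labels' protocols, protoplasts that took up no DAPI, a dye that enters dead cells, were sorted and loaded on a droplet-based Chromium instrument with the 10x Genomics 3' kit. The labels give 2 genotypes, bri TRIPLE and bri T-RESCUE, with 1 library each. The genotype label set the group. The free-text description of the bri T-RESCUE library carries the name bri TRIPLE, while its title and genotype label both read bri T-RESCUE, and no value used here could check which is right.

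The authors' deposited files used here are lists, not measurements. Each library has 1 list of cell barcodes, the 16-base sequences that mark the droplets kept as cells, and 1 list of features, the genes that reads could be assigned to. Per the submitters' processing notes, the reads were processed with Cell Ranger against TAIR10. The version, the cell-calling settings and the annotation release are not given in the sources used here. By their deposited names, the lists belong to the filtered matrix, so droplets that were not called as cells had been removed. Counts of transcripts per gene and cell were not analysed here, so the depth per cell is unknown. No expression level, cell cluster, share of a cell type or doublet rate was computed.

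Barcodes were counted per library and given exact 95% Poisson intervals, which cover counting error only. Barcode sequences were compared within and between the libraries, exactly and with 1 substitution allowed. The number shared by chance was computed in the manner fixed before the data were examined, by multiplying the base composition at each of the 16 positions, with 1000 resamples. A second expectation was chosen after seeing the data. In it, the first 7 and the last 9 bases of each barcode were re-paired at random within each library, with 10000 shuffles. This split was chosen because it gave the highest expectation of the 15 possible splits. The expectation for this split, with a Poisson p, was tested on simulated data. These had the list sizes of these libraries and were drawn evenly from a pool holding every combination of the observed parts. The shuffles were not run on them, and a smaller or unevenly used pool was not simulated. Over 20 simulated pairs, 30 planted shared barcodes gave a mean excess of 30.5 (SD 5.5), and no planted barcodes gave a mean excess of 0.22 (SD 4.61). Of the pairs with no planted barcodes, 0 of 20 had a Poisson p under 0.05. Base composition was given in percent with exact binomial intervals.

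Features were matched by locus identifier to the gene table of the TAIR10.1 RefSeq annotation. This is a later release than the TAIR10 named by the submitters, so it was used only for gene names and classes, and no coordinates are given. All 32548 nuclear loci matched, while 1716 other features did not match by locus. They comprise 285 organelle genes, 1429 non-coding RNAs with ENSRNA identifiers and 2 added features. The genes named are those of lists fixed before the data were examined, with 11 brassinosteroid signalling genes, 9 genes of brassinosteroid synthesis and breakdown, and 28 markers of 10 root cell classes. The reference table pairs 46 of these 48 symbols with the same locus, and the pairing of the cortex markers CO2 and AED3 with their loci was set when the lists were fixed. Loci outside these lists are named where they carry the same name as a listed gene. A locus classed as a pseudogene in TAIR10.1 is named because it alone of its kind was listed. A few miRNA entries are named to illustrate a pairing of identifiers. All of these were chosen after the list had been seen. With 1 library per genotype, no test between genotypes was made. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.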

Results

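The study addressed the action of brassinosteroids, plant steroid hormones that drive cell elongation and division, in the Arabidopsis root at the level of single cells. The labels give the genotypes only by name, as bri TRIPLE and bri T-RESCUE. From background knowledge of the study, and from no source used here, bri TRIPLE is understood to lack the receptor kinase BRI1 and its homologues BRL1 and BRL3, and bri T-RESCUE to be that mutant with BRI1 returned in the phloem. The bri TRIPLE library held 10574 cell barcodes (exact 95% Poisson interval 10373 to 10777). The bri T-RESCUE library held 12335 (12118 to 12555), which is 1761 more, or 1.17 times as many. Each genotype had 1 library, so this difference has no replicate check, and the number of barcodes depends on how many protoplasts were loaded and on cell calling. Counts per gene were not analysed here, and no gene can be called higher or lower in either genotype.

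Every gene of the brassinosteroid pathway fixed for this comparison was listed for both libraries, because both were assigned against the same list of 34264 features. A listing does not show that reads were counted for a gene. All 11 signalling genes were listed by locus. They included the receptor BRI1 (AT4G39400, on chromosome 4), its homologues BRL1 (AT1G55610, on chromosome 1), BRL2 (AT2G01950, on chromosome 2) and BRL3 (AT3G13380, on chromosome 3), and the co-receptor kinase BAK1 (AT4G33430). The receptor inhibitor BKI1, the receptor-associated kinase BSK1 and the phosphatase BSU1 were listed, as were the transcription factors BZR1 and BES1. The GSK3-like kinase BIN2 (AT4G18710), which represses the pathway, stood under the name ASK7. That name was carried by 2 features, the other being AT3G21840. Of the 11 signalling genes, 10 were found at the right locus by their usual symbol.

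All 9 genes of brassinosteroid synthesis and breakdown were also listed by locus, but only 3 of them, DET2, ROT3 and CYP90D1, were found by symbol. The steroid hydroxylase DWF4 (AT3G50660) stood as CYP90B1 and CPD (AT5G05690) as CYP90A1. The oxidases BR6OX1 and BR6OX2, which carry out the last steps to active hormone, stood as CYP85A1 and CYP85A2, and DWF1 as DIM. BAS1 (AT2G26710), a cytochrome P450 that inactivates brassinosteroids, stood as CYP734A1. The symbol BAS1 was instead assigned to AT3G11630, a chloroplast peroxiredoxin gene. A lookup of BAS1 by symbol in this list would therefore return the peroxiredoxin.

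The 28 markers of 10 root cell classes were all listed by locus, and 15 of them were found by symbol at that locus alone. The endodermis markers SCR, MYB36 and CASP1 and the epidermis markers GL2 and WER were found in full. Among the 4 phloem markers, APL and SUC2 were found. CVP2 (AT1G05470), a phosphoinositide phosphatase gene, stood as IP5P6, and the protophloem regulator BRX (AT1G31880) stood as NLM9. Among the 3 xylem markers, AHP6 was found, VND7 stood as NAC030 and TMO5 as BHLH32. The cytokinin receptor WOL stood as AHK4, the root hair regulator RHD6 as BHLH83, the root hair expansin EXP7 as EXPA7, the mitotic cyclin CYCB1;1 as CYCB1-1, and the cortex marker CO2 only under its locus identifier, AT1G62500.

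The symbols of 4 markers were also carried by a second gene. SMB, a root cap transcription factor (AT1G79580), shared its name with AT4G20440. BRN1, another root cap factor (AT1G33280), shared its name with AT4G03110. The stem cell regulators PLT1 (AT3G20840) and PLT2 (AT1G51190) shared theirs with AT2G16120 and AT2G16130, genes of polyol transporters. Across the whole list, 366 names were used more than once and covered 1712 features. Of these features, 578 were nuclear protein-coding genes and 508 were non-coding RNAs that all carried the name 5S_rRNA.

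The list held 2 features added to the plant genome, named for the yellow fluorescent proteins Venus and Citrine, which serve as reporters. Both proteins derive from the same jellyfish protein. If the 2 listed sequences were close, reads could fit either, and the counts at both would be uncertain. The sequences were not examined here. The same 2 features were offered to both libraries. Nothing in the lists shows whether either reporter was expressed in bri TRIPLE or bri T-RESCUE.

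The nuclear genome was covered for protein-coding genes and hardly at all for pseudogenes. All 27444 nuclear protein-coding loci of TAIR10.1 were listed, as were all 3480 long non-coding RNA loci and all 79 antisense RNA loci. Of 4843 loci that TAIR10.1 classes as pseudogenes, 1 was listed, PMI15 (AT5G38150), named here after the list was seen. Its class was taken from that gene table and was not checked further. None of the 508 loci of the miscellaneous RNA class was listed. The list also held 133 chloroplast and 152 mitochondrial genes. By chromosome, the nuclear loci numbered 8656 on chromosome 1, 5174 on chromosome 2, 6435 on chromosome 3, 4921 on chromosome 4 and 7362 on chromosome 5.

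**Figure D1:**
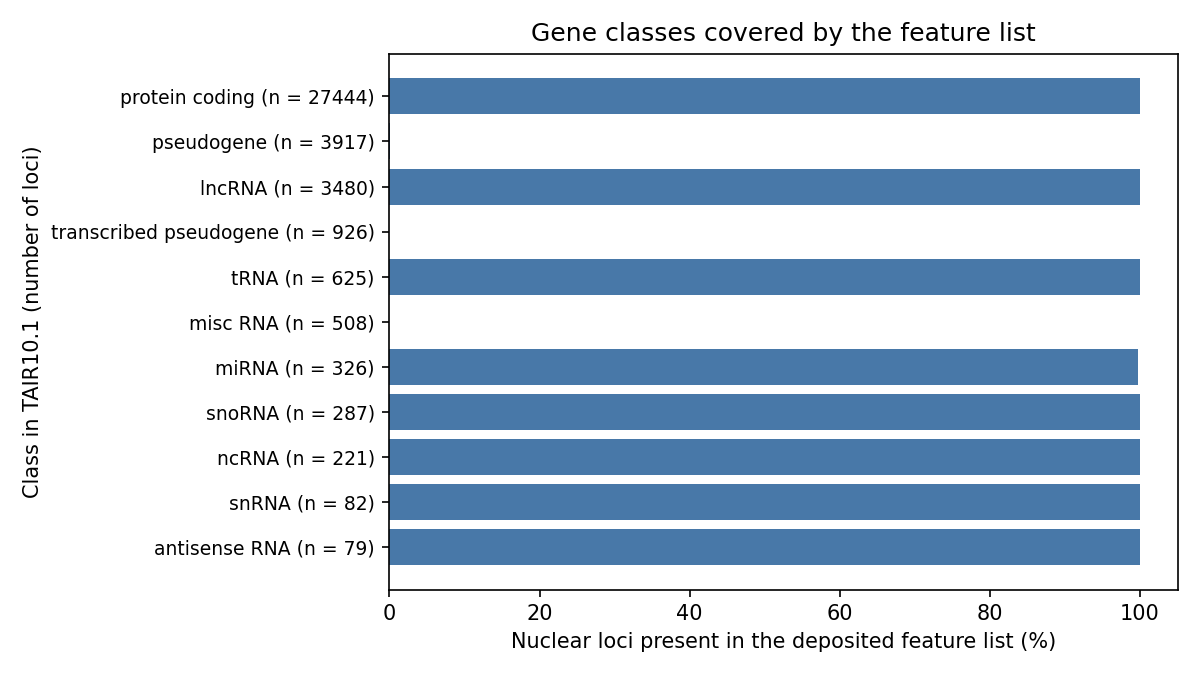
Percent of the nuclear loci of each TAIR10.1 class (bars, with the number of loci n beside each name) that were present in the feature list common to both libraries; classes with fewer than 50 loci are left out. Protein-coding and long non-coding RNA loci stand at 100%, transcribed pseudogenes and miscellaneous RNA at 0%, and other pseudogenes, with 1 of 3917 listed, too close to 0% to be seen.

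The barcodes of the bri TRIPLE and bri T-RESCUE libraries were compared to see whether they were independent. Within each library every barcode was distinct, and 0 lay 1 substitution from another. The libraries had 59 barcodes in common (exact 95% Poisson interval 44.9 to 76.1), which is 0.558% of the bri TRIPLE barcodes and 0.478% of the bri T-RESCUE barcodes. The expectation fixed beforehand, from the base composition at each position, was 0.031. It ignores that barcodes are built from a limited set of parts. The barcodes held 960 different first parts of 7 bases and 3837 different last parts of 9 bases. Re-pairing these parts at random gave 35.1 shared barcodes (SD 5.9 over 10000 shuffles, range 15 to 62). As many as 59 were reached in 1 shuffle (one-sided permutation p = 0.0002). The observed number was 1.67 times the 35.4 expected (1.27 to 2.15 from the Poisson interval). The permutation compares these libraries and not the genotypes. It assumes that every first part could join every last part, which was not checked. A pool lacking some of these combinations would also raise the shared number, so this p alone cannot show a link between the libraries.

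**Figure D2:**
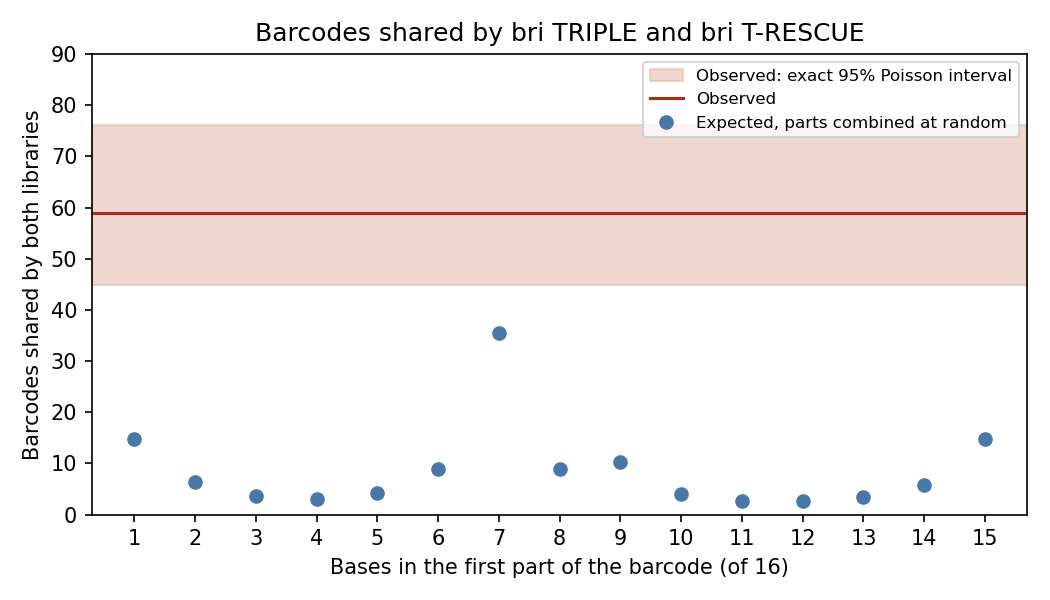
Number of barcodes shared by the bri TRIPLE and bri T-RESCUE libraries: the observed 59 (line) with its exact 95% Poisson interval (band), and the number expected (points) when the barcode is divided after the given number of bases and its parts are combined at random. The highest expectation, 35.4 after 7 bases, lies below the band.

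The barcodes of both libraries had nearly even base composition. Over the 16 positions and both libraries, the share of a base ranged from 22.1% to 27.9%. The largest difference was in A at position 4, counted from the first base of the barcode, with 26.1% in bri TRIPLE and 24.8% in bri T-RESCUE. The exact 95% binomial intervals of the libraries overlapped for all 64 combinations of base and position, without correction for their number. Such overlap is not a test of the difference between the libraries, and none was made. The 64 combinations are not all separate. In both libraries the shares at position 9 repeated those at position 8 under other bases, as with A at position 8 and G at position 9.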

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

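Most of the alternatives tried could not move their value and say nothing about its stability. Each library had 1 suffix and 0 barcodes 1 substitution from another, and 0 barcodes lay 1 substitution apart across the libraries, so removing suffixes or near-identical barcodes removed nothing (10574 and 12335 barcodes) and allowing 1 substitution added nothing to the 59 shared. Leaving out the 59 shared barcodes was too small a change to move base composition past its interval. Nuclear loci alone numbered 32548 of the 34264 features. Matching the fixed genes by symbol found 28 of the 48 listed by locus, because 15 symbols were absent, 1 named another locus alone and 4 named a second locus too. The number of shared barcodes expected by chance was 0.031 from the composition per position and 35.4 with the first 7 and last 9 bases drawn independently, the latter chosen after seeing the data. The observed 59 exceeded both. The alternatives set out beforehand for gene expression (another scaling, no filter on low counts, no minimum of transcripts per cell) were not run, since counts per gene were not analysed here. No paired analysis was possible because each genotype had 1 library and no result came from a test between genotypes. The lists carry no depth, so the precision of any expression value cannot be stated.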

Other observations

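The tests of what lies behind the excess of shared barcodes, and the even-use expectation they rest on, were chosen after the result was seen, and the test of the miRNA entries was written before its result was seen.

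The microRNA genes of the feature list came in pairs. The list held 325 miRNA features with AGI locus identifiers and 325 with ENSRNA identifiers, and each of the latter had a namesake among the former, as with MIR165A (AT1G01183) and ath-MIR165a. Names were matched without the ath- prefix and without regard to case, and 0 were identical as written. By this rule 125 matched the name given in the list and the other 200 only the symbol of the locus in the TAIR10.1 gene table. MIR165A encodes a microRNA that targets HD-ZIP III transcription factors, which pattern the root vasculature. A candidate explanation is that each miRNA locus was listed under 2 identifiers. If so, namesakes should be neighbours in a list that largely follows locus order (89.3% of successive AGI loci ascended). Of the pairs, 99.1% (322 of 325) stood on adjacent lines, against at most 1.85% in 1000 random re-pairings. The exceptions, ath-MIR5649a, ath-MIR5995b and ath-MIR5595a, stood 2 or 3 lines from their namesakes. This fits the explanation for those 322 pairs. Whether reads from miRNA precursors were then left out as ambiguous was not tested, and zeros at these loci would need that check.

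More barcodes were shared by the bri TRIPLE and bri T-RESCUE libraries than even use of the barcode parts gave, 59 against 35.41. The values argue against uneven use of the parts, each taken singly, as the cause. The random re-pairing had already kept each library's own use of both parts, with 35.39 expected, so the values below add little to it. How often whole barcodes occur in the pool was not tested. The variance over the mean of the number of barcodes per part was 1.02 for the first parts and 0.977 for the last, and their upper 95% bounds allow an expectation of at most 35.7 if both libraries shared the same uneven use, below the lower bound of 44.9 on the observed number. A barcode pool smaller than the product of its parts (3683520 combinations) may account for the excess if it held about 2210680 barcodes (1713800 to 2904030), but the kit's own list was not used here. Reads carried from one library into the other could also account for it, and would then concern about 23.6 barcodes, 0.223% of those of bri TRIPLE. With neither the kit's list nor counts per barcode used here, the last 2 explanations cannot be told apart, and no biological explanation was tested.

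Of the other non-coding RNAs with ENSRNA identifiers, 508 features carried the name 5S_rRNA and 344 were named as tRNAs, beside 625 tRNA loci with AGI identifiers.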
